A study of Mus musculus with 21 samples.

How the data were processed

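The samples were mouse ESCs cultured for 48 h in SL or SL2i medium with 0.2 mM pyruvate, in 8 groups of 2 or 3 libraries (21 libraries). The expansion of the medium names and the reading of chr8A as a control line were taken from usage in this field, since the labels give only the short names. Per the labels, libraries were made with a stranded poly(A) kit from 500 ng of RNA with a RIN of at least 9.3 and 8 PCR cycles. Per the submitters' processing notes, the authors aligned reads to the mouse genome build GRCm39 with DRAGEN 3.10 and counted them per gene with featureCounts of Subread. The strand setting of the counting is not given in the sources used here. The deposited tables hold raw counts per gene in 2 tables of 40838 genes each, one with the vector and LbNOX libraries and one with the 15 other libraries, and the tables were treated separately. All 21 count columns were used. Gene symbols came from the tables, and 96.5% of the gene identifiers were matched to the RefSeq annotation of GRCm38.p6, an older build than the authors', so only names, chromosomes and gene order were taken from it. Mitochondrially encoded genes were not analysed here.

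Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, robust dispersions and a quasi-likelihood F test with 1 mean per group. The 6 LbNOX table libraries formed one fit (16119 genes tested), and the 15 others formed a second fit (17178 genes), in which all groups share one estimate of spread. P values were adjusted by the Benjamini-Hochberg procedure within each comparison, and an adjusted p under 0.05 was called. Changes are log2 fold changes ± standard error, and CPM values are TMM-normalized means ± SD. Replicates are libraries of the same line, so p values measure only the spread between these libraries, which may be technical. They carry over to other lines only as far as the 2 clones go. Levels set across the 2 tables were normalized separately and not tested. Where a group had no read of a gene, the change is given as at least the ratio to 3 counts over the group. Where it had 1 to 3 reads, it is given as a ratio with a 95% exact binomial interval. Such floors and intervals cover counting error only.

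Gene lists, 28 in number, were written before the data were examined, as were the groups, the tests, the rule for naming genes and most of the alternatives. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists. The same test was repeated with the correlation estimated from the data, because a preset value can be too small for genes that vary together. Counts of members that rose or fell use the adjustment over all genes, and a second count uses the adjustment over the list alone. Named genes were Slc16a1, the 6 that rose most and the 6 that fell most per comparison among called genes with a mean of at least 3 log2 CPM, libraries that did not overlap between groups and a proper symbol, up to 4 members of each list described with the smallest adjusted p plus marker genes fixed in advance, and the 5 largest interactions. Genes so named in one comparison were followed in the others. Pnma5, Efhc2, Thsd7a and Samd9l fall outside the rule and were chosen after their values were seen, as were Enpp2 and Myl9 in the closing section. A few genes that met the rule or a test's criteria are not reported here, and no others took their place.

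Shared sequence was measured as the percent of a gene's 30-base words that also occur in another gene of the reference. A gene with at least 5% is given with that percent, and its value is uncertain because reads may belong to the other gene. Overlap between the clones was set against the number for independent lists and against 20 simulations in which unchanged groups were compared with the same control libraries.

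Median standard errors of a log2 fold change were 0.0671 between LbNOX and vector, 0.0527 for clone 1 against chr8A in SL and 0.0678 for the media. The pipeline was tested on simulated data with planted changes. It recovered 82.1% of 1.5-fold and 88.1% of 2-fold changes between LbNOX and vector, with 19 false calls of 198. For clone 1 it recovered 79.1% and 88.1% in SL (9 false of 186), and 65.7% and 76.1% in SL2i (9 of 161). For the media it recovered 80.6% and 88.1% (7 of 184), and for the interaction 58.2% and 74.6% (13 of 160). Each simulation held many changed genes, and genes were drawn independently. Recovery may be lower where few genes change or libraries vary together, as between LbNOX and vector. A planted list shift of 0.3 was found, and 5 of 99 unchanged lists had an unadjusted p under 0.05.

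Alternatives were RLE factors in place of TMM, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a block for the replicate number, only the groups compared in the fit, and each library left out in turn. For the lists they were an estimated correlation and fry of limma. Added after the data were seen were only genes with under 5% of shared words, all 15 libraries thinned to 9784408 reads, the LbNOX fit without the 2 libraries at the far end of its component 1, and RLE factors in the chromosome check.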

Results

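Poly(A)-selected RNA was sequenced from mouse embryonic stem cells (ESCs), which are pluripotent cells that can be grown in culture. The 21 libraries formed 8 groups, all grown for 48 h with 0.2 mM pyruvate and 10% dialyzed serum. SL was read as serum with leukemia inhibitory factor (LIF), and SL2i as the same with 2i, a pair of inhibitors of GSK3B and MEK. One table held 3 libraries of cells with an empty vector and 3 of cells with LbNOX, a bacterial enzyme that oxidizes NADH to NAD+ and forms water, all in SL. The other table held a control line called chr8A and SLC16A1 clones 1 and 2, with 3 libraries each in SL and 2 each in SL2i. Slc16a1 encodes the monocarboxylate transporter MCT1, which carries pyruvate and lactate across the plasma membrane. How the clones were altered is not given in the sources used here. Total counts per library were 16521594 to 30008895 in the LbNOX table, 15802072 to 30145771 in the SL libraries of the other table and 9784408 to 10908368 in the SL2i libraries. The study's title concerns the dependence of cells on pyruvate from outside, so transcripts of pyruvate and NADH metabolism and of pluripotency were followed.

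Slc16a1 (Entrez gene 20501) was transcribed in every group, and its level was lower in both clones than in chr8A. In SL it stood at 198 ± 2.99 CPM (mean ± SD, n = 3) in chr8A, 171 ± 10.4 in clone 1 (n = 3) and 93.6 ± 2.65 in clone 2 (n = 3). In SL2i it stood at 162 ± 6.96 in chr8A (n = 2), 123 ± 0.732 in clone 1 (n = 2) and 78.6 ± 0.122 in clone 2 (n = 2). The log2 fold change of Slc16a1 against chr8A was -0.21 ± 0.033 (SE) in clone 1 and -1.08 ± 0.034 in clone 2 in SL. In SL2i it was -0.40 ± 0.050 in clone 1 and -1.04 ± 0.053 in clone 2. All 4 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p being 2.7e-07. An edit can remove a protein and leave its mRNA, so these levels do not measure the transporter. Vector and LbNOX cells held 155 ± 3.40 and 150 ± 6.58 CPM of Slc16a1 (n = 3 each), a log2 difference of -0.05 ± 0.046 that did not pass (adjusted p = 1).

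**Figure D1:**
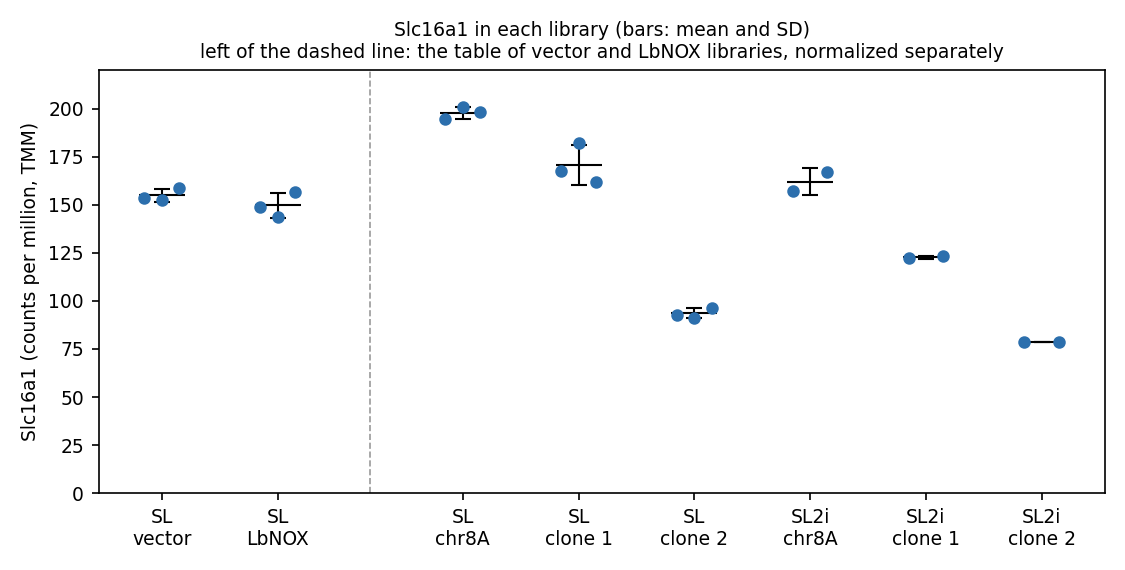
Slc16a1 in CPM (TMM-normalized) in each of the 21 libraries by group, with points for libraries and bars for the mean and SD. Clone 2 lay at 91.4 to 96.5 in SL and near 78.6 in SL2i, below every chr8A library; the tables on either side of the dashed line were normalized separately.

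LbNOX and vector cells were compared to see which transcripts differ when NADH is oxidized by an added enzyme. Few did, and all of the lower ones lay on the sex chromosomes. The Y-linked RNA helicase gene Ddx3y fell by 2.19 ± 0.21 on the log2 scale (6.66 ± 0.542 CPM in vector and 1.47 ± 0.477 in LbNOX cells, mean ± SD, n = 3 each; adjusted p = 0.0022, edgeR). Uty, a Y-linked relative of histone demethylases, changed by -1.80 ± 0.20 (adjusted p = 0.0044). On the X chromosome, Klhl13, a ubiquitin ligase adaptor, dropped by 0.88 ± 0.093 (adjusted p = 0.0097). Pnma5 changed by -2.34 ± 0.29 (adjusted p = 0.010), which is uncertain because 29.6% of its sequence words occur in another gene. Efhc2 had 3 reads over the LbNOX libraries and 50 over the vector libraries, a 20.9-fold lower level (95% exact binomial interval 6.76 to 105; adjusted p = 0.022). The gene that rose was Pou4f2 on chromosome 8, a transcription factor of sensory neurons, by 0.56 ± 0.081 (adjusted p = 0.033). For each of the 6 genes every LbNOX library lay on one side of every vector library, which chance gives for 10% of unselected genes with 3 against 3. The 6 were picked by their difference in these same libraries, so this is no separate support.

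**Figure D2:**
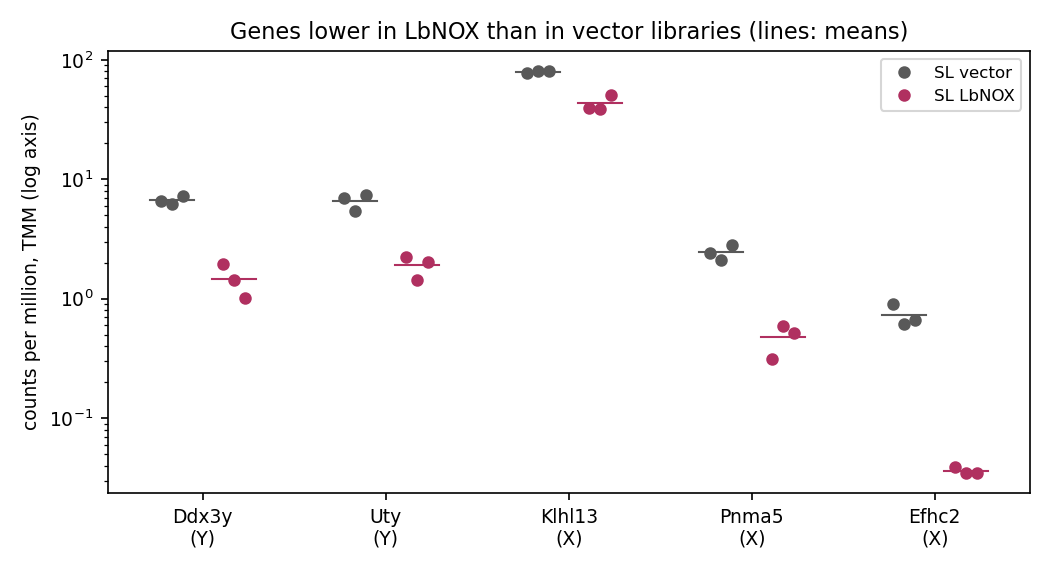
CPM (TMM-normalized, log axis) of the 5 genes lower in LbNOX than in vector cells, with points for the 3 libraries of each group and lines for their means; Y or X gives the chromosome. Ddx3y lay at 6.20 to 7.26 in vector and 1.01 to 1.96 in LbNOX libraries.

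Of 16119 genes tested between LbNOX and vector, these 6 passed (1 higher, 5 lower) and 605 had an unadjusted p under 0.05. The count hung on single libraries. It was 0 without SL vector replicate 3 (438 genes at an unadjusted p under 0.05, edgeR; DESeq2 on all 6 libraries called 14), 2 without vector replicate 1, 2 without LbNOX replicate 1, 3 without LbNOX replicate 2 and 13 without LbNOX replicate 3. On component 1 vector replicate 2 and LbNOX replicate 3 lay apart from the other 4 libraries, and without both, a test chosen after the data were seen, 49 genes passed (22 higher, 27 lower). Without vector replicate 3 the adjusted p was 0.062 for Ddx3y and 0.094 for Uty, over ranges across all settings of 2.1e-23 to 0.062 and 3.5e-17 to 0.094. The Klhl13 call ended without vector replicate 1, vector replicate 3 or LbNOX replicate 1 (range 2.4e-39 to 0.11), and the Pou4f2 call ended under 7 settings (range 1.6e-08 to 0.32). Those of Pnma5 and Efhc2 ended under 5 and 6 settings (ranges 2.2e-09 to 0.15 and 4e-05 to 0.23). The lists of glycolysis genes (camera adjusted p = 0.37), genes of NADH shuttles and NAD metabolism (adjusted p = 0.744) and genes of pyruvate and lactate transport and use (adjusted p = 0.942) did not pass. Endoderm genes lay higher and imprinted genes lower as lists (adjusted p = 0.00974 each), and neither call held with an estimated correlation (adjusted p = 0.583 and 0.632). Adjusted over the list alone, 2 of 14 endoderm genes were higher and 3 of 22 imprinted genes lower. Examples were the basement membrane gene Col4a1 at 0.24 ± 0.045 (adjusted p = 0.17) and the imprinted RNA Meg3 at -0.47 ± 0.10 (adjusted p = 0.42).

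In chr8A cells, SL2i was compared with SL to describe the medium itself. Naive pluripotency genes, which mark the preimplantation state, rose as a group: 16 of 18 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 3.8e-17, and 0.000762 with an estimated correlation). The transcription factor genes Tfcp2l1, Klf4 and Esrrb rose by 2.98 ± 0.032, 2.94 ± 0.038 and 1.58 ± 0.032 on the log2 scale (n = 2 and 3), and Nanog by 2.14 ± 0.031 (11.1% of its words shared with other genes). The core factors Pou5f1 (5.40% shared) and Sox2 differed less, at 0.38 ± 0.031 and 0.31 ± 0.033. All 12 formative and primed pluripotency genes fell (all 12 adjusted over the list alone; adjusted p = 5.13e-09, and 0.0149 with an estimated correlation). Among them were the POU factor gene Pou3f1 (-5.54 ± 0.11), the homeobox gene Otx2 (-2.68 ± 0.12) and the DNA methyltransferase gene Dnmt3b (-2.91 ± 0.037; 16.1% shared). Of 19 genes read as output of ERK signaling, the pathway that MEK activates, 17 fell and 1 rose (the same adjusted over the list alone; adjusted p = 6.13e-11, and 0.00407 with an estimated correlation). The feedback inhibitor gene Spry4 fell by 5.04 ± 0.089. The phosphatase genes Dusp6 and Dusp4 stood at -4.47 ± 0.083 and -6.64 ± 0.15.

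Targets of Wnt signaling, which GSK3 restrains, split in SL2i: 5 of 12 rose and 3 fell (the same adjusted over the list alone). The Wnt deacylase gene Notum rose by 3.85 ± 0.083, the homeobox gene Cdx1 by 5.56 ± 0.16 and the negative regulator gene Axin2 by 3.44 ± 0.072. The list lay higher (adjusted p = 0.0197), a call that ended with an estimated correlation (adjusted p = 0.0869) and without the count filter (0.247; lowest over the camera settings 0.0104). Imprinted genes mostly fell, 19 of 21 with 2 rising (the same adjusted over the list alone; adjusted p = 1.49e-09, and 0.0149 with an estimated correlation). The retrotransposon-derived placental gene Peg10 (-4.69 ± 0.047), the growth factor gene Igf2 (-6.25 ± 0.12) and Mest (-2.69 ± 0.064) fell. The zinc finger gene Plagl1 rose by 3.21 ± 0.044. Of 11 genes listed as fibroblast markers, 10 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.00588, and adjusted p = 0.0869 with an estimated correlation), including the collagen genes Col1a1 at -3.67 ± 0.18 and Col1a2 at -4.56 ± 0.29.

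Metabolic genes moved in several directions between SL2i and SL. The pyruvate dehydrogenase kinase gene Pdk1 (-2.51 ± 0.048), the lactate exporter gene Slc16a3 (-2.43 ± 0.062) and Emb (-3.43 ± 0.055), a chaperone of monocarboxylate transporters, fell. Slc16a1 fell by 0.29 ± 0.040. The list of genes of pyruvate and lactate transport and use as a whole did not pass (10 of 23 rose and 11 fell, all 21 also adjusted over the list alone; adjusted p = 0.569). Of 30 genes of the ATF4 amino acid stress response, 23 fell and 7 rose (the same adjusted over the list alone; adjusted p = 0.00416, and adjusted p = 0.177 with an estimated correlation). The mTOR inhibitor gene Ddit4 (-2.93 ± 0.059) and the serine synthesis gene Psat1 (-0.94 ± 0.033) fell, whereas the asparagine synthetase gene Asns rose by 1.31 ± 0.032. Nuclear-encoded respiratory chain genes lay higher, with 61 of 70 rising (62 adjusted over the list alone; adjusted p = 1.77e-11, and adjusted p = 0.0982 with an estimated correlation). Their size followed shared sequence: the 14 members with at least 20% of their words in other genes had a median log2 fold change of 1.42, and the 39 members under 5% had 0.35. All 9 genes measured of the two-cell-like state rose (all 9 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.126 with an estimated correlation). They are copies of one another: Zscan4a shares 77.4% of its words with other genes and Zscan4d 66.0%, so their values are uncertain.

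Of 17178 genes tested between SL2i and SL, 12510 passed, 6194 higher and 6316 lower in SL2i, of which 2477 and 3441 by at least 2-fold. The near balance depended on shared sequence. Among the 13386 genes under 5% of shared words, chosen after the data were seen, 9967 passed, 4484 higher and 5483 lower. At 3 log2 CPM or more, 58.5% of the 270 genes with at least 50% of shared words differed by 2-fold or more. Of the 8582 genes under 5%, 21.4% did. The largest rises by the naming rule were those of the homeobox gene Crxos (2 reads in SL and 1073 in SL2i, a ratio of 1980 with an interval of 546 to 16300; 28.5% shared), the glycine receptor gene Glra1 (7.57 ± 0.22) and the channel gene Trpm1 (7.23 ± 0.18). Next came Elobl (6.35 ± 0.15; 19.2% shared), the aldehyde oxidase gene Aox3 (6.34 ± 0.16) and the bicarbonate transporter gene Slc4a5 (5.97 ± 0.097). The largest falls were of genes without a read in SL2i. The carbonic anhydrase gene Car4 was at least 534-fold lower, the smooth muscle actin gene Acta2 482-fold, Fermt1 172-fold, the metal transporter gene Slc39a8 136-fold and Jakmip2 95.2-fold, each against 3 reads over the SL2i group. The SL2i libraries were also the shallower ones. At equal depth, chosen after the data were seen, 11540 of 15769 genes still passed (5697 higher, 5843 lower), which argues against depth alone as the source of the count. Medium and library set cannot be separated.

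Both SLC16A1 clones in SL were compared with chr8A in SL, which asks what a change at this transporter gene leaves in the transcriptome. Naive pluripotency genes were lower and formative ones higher than in chr8A. Of 18 naive genes, 12 fell and 1 rose in clone 1 (13 and 1 adjusted over the list alone; camera adjusted p = 7.24e-13, and 0.00267 with an estimated correlation). In clone 2, 10 fell and 3 rose (the same adjusted over the list alone; adjusted p = 0.000567, and 0.0452 with an estimated correlation). In clones 1 and 2 the factor gene Klf2 stood at -0.56 ± 0.036 and -0.48 ± 0.035, Tfcp2l1 at -0.39 ± 0.031 and -0.35 ± 0.030, and Esrrb at -0.28 ± 0.030 and -0.13 ± 0.029. Of 12 formative and primed genes, 10 rose in clone 1 and 12 in clone 2 (the same adjusted over the list alone; adjusted p = 7.44e-17 and 1.15e-24, and 0.00417 and 0.00256 with an estimated correlation). Lef1, a transcription factor of Wnt signaling, rose by 1.49 ± 0.080 and 1.70 ± 0.076, the N-cadherin gene Cdh2 by 0.81 ± 0.080 and 0.87 ± 0.076, and Otx2 by 0.32 ± 0.059 and 0.69 ± 0.055. ERK output genes rose too, 11 of 19 in clone 1 with 1 falling and 12 in clone 2 with 2 falling (the same adjusted over the list alone; adjusted p = 1.61e-07 and 1.61e-05, and 0.00891 and 0.0123 with an estimated correlation). Among them were Myc (0.37 ± 0.045 and 0.37 ± 0.043) and the cyclin gene Ccnd1 (0.28 ± 0.031 and 0.33 ± 0.030). Of 12 Wnt targets, 4 rose in each clone and 1 fell in clone 2 (4 and, in clone 2, 4 and 2 adjusted over the list alone; adjusted p = 0.000117 and 0.0269, and adjusted p = 0.0101 and 0.0837 with an estimated correlation). In clone 2 the median and mean of that list, -0.06 and -0.04, went against its test, and the call also ended without the count filter (adjusted p = 0.33; lowest over the camera settings 0.00236).

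The stress and lipid lists moved as well in SL. ATF4 genes mostly rose, 17 of 30 in clone 1 with 1 falling (20 and 1 adjusted over the list alone) and 16 in clone 2 with 4 falling (17 and 4), with adjusted p = 2.48e-08 and 0.000213, and adjusted p = 0.0609 and 0.152 with an estimated correlation. The secreted glycoprotein gene Stc2 rose by 0.49 ± 0.063 and 0.52 ± 0.060 and the glutathione-degrading enzyme gene Chac1 by 0.43 ± 0.061 and 0.37 ± 0.059. Cholesterol synthesis genes fell, 8 of 25 in clone 1 (10 adjusted over the list alone; adjusted p = 0.00495, and adjusted p = 0.162 with an estimated correlation). In clone 2, 17 fell and 1 rose (the same adjusted over the list alone; adjusted p = 2.59e-08, and 0.0116 with an estimated correlation). The regulator gene Srebf2 stood at -0.14 ± 0.028 and -0.23 ± 0.028. In clone 2, 10 of 14 fatty acid synthesis genes fell and 1 rose (adjusted p = 4.02e-05), including the desaturase gene Scd1 at -0.49 ± 0.034 (8.45% shared). There 5 of 14 endoderm genes fell (adjusted p = 0.000142), including the collagen gene Col4a2 at -0.46 ± 0.042. These 2 counts were the same adjusted over the list alone, and each list had an adjusted p of 0.0116 with an estimated correlation. The list of pyruvate and lactate transport and use did not pass in either clone (adjusted p = 0.813 and 0.688). Of its members, Slc16a3 rose by 0.23 ± 0.036 and 0.28 ± 0.035 and Emb by 0.20 ± 0.030 and 0.35 ± 0.030.

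Of 17178 genes, 2850 passed in clone 1 (1516 higher, 1334 lower) and 4618 in clone 2 (2452 higher, 2166 lower) in SL, and most of these changes were small: 34 and 46 genes were at least 2-fold higher, 59 and 107 at least 2-fold lower. Without SL chr8A replicate 3 the balance turned, to 1005 higher and 1108 lower in clone 1 and 1735 and 1958 in clone 2. In SL the chr8A libraries varied more among themselves than those of either clone. The chi-square per degree of freedom between 2 libraries was 4.84 to 14.14 in chr8A, highest for replicates 1 and 3. Within the clones it was 1.88 to 4.51. The list tests were not repeated with a library left out. DESeq2 called 1774 and 2876 genes, and equal depth, chosen after the data were seen, gave 1854 and 2900. The imprinted zinc finger gene Peg3 fell most in clone 1 (-2.18 ± 0.033) and fell as much in clone 2 (-2.19 ± 0.032). It went from 439 ± 5.60 CPM in chr8A to 96.8 ± 3.88 and 96.2 ± 4.30 (mean ± SD, n = 3 each). Plagl1 stood at -0.88 ± 0.056 in clone 1 and -7.31 ± 0.13 in clone 2, where it was nearly silent with 20 reads against 3182. Imprinted genes went both ways: of 21, 8 rose and 6 fell in clone 1, and 6 rose and 5 fell in clone 2 (9 and 7, and 6 and 6, adjusted over the list alone). As a list they did not pass in clone 1 (camera adjusted p = 0.0698) and were called lower in clone 2 (3.45e-05, and 0.03 with an estimated correlation). In clone 2 the list had a mean of -0.513 but a median of 0.016, so most members did not lie lower. The other large falls in both clones were of the oocyte gene Khdc3 (-1.04 ± 0.12 and -0.97 ± 0.11) and Plac8 (-0.87 ± 0.079 and -0.84 ± 0.074). The water channel gene Aqp3 (-0.81 ± 0.088 and -0.66 ± 0.079) and Stard8 (-0.71 ± 0.11 and -0.82 ± 0.10) fell in both as well. Tmem40 fell in clone 1 (-1.05 ± 0.13), and Xaf1 and Got1l1 in clone 2 (-1.88 ± 0.37 and -1.06 ± 0.093). After Lef1 and Cdh2, the large rises in both clones were of the Wnt target gene Sp5 (1.14 ± 0.15 and 0.71 ± 0.15) and the activin antagonist gene Fst (0.83 ± 0.12 and 0.80 ± 0.12). So were those of Arhgef26 (0.75 ± 0.11 and 0.72 ± 0.11) and Akap17a (0.71 ± 0.074 and 0.70 ± 0.071). Zrsr1 and Nfib rose in clone 1 by 0.79 ± 0.091 and 0.78 ± 0.13, and Phf14 (16.7% shared), Ttn and Ndufa4 in clone 2 by 0.85 ± 0.041, 0.75 ± 0.082 and 0.73 ± 0.031. The clones shared 2103 calls of the same sign (1119 higher, 984 lower) and 20 of opposite sign, and 1338 of the same sign in DESeq2 and 1288 at equal depth. Independent lists of these sizes would share 216.4 higher and 168.2 lower calls, and unchanged groups simulated against the same controls shared at most 1. Across genes of at least 3 log2 CPM the fold changes of the clones correlated with r = 0.743 and a covariance of 0.0202, against means of 0.47 and 0.00209 (highest 0.538 and 0.00274) in the simulations. The 3 controls could not be split in a way that leaves each part 2 libraries, so part of the excess may come from shared controls. Simulated genes varied independently and no simulated line differed. The simulations therefore do not give the overlap that 2 unrelated lines would show against 1 control line.

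The same comparison in SL2i gave larger changes. Trophoblast genes rose, 6 of 9 in each clone (7 of 9 in each adjusted over the list alone; adjusted p = 1.27e-10 and 4.8e-10, and 0.00904 and 0.0101 with an estimated correlation). Among them were the keratin genes Krt18 (2.54 ± 0.16 in clone 1 and 2.51 ± 0.16 in clone 2; 12.4% shared) and Krt7. The latter had 2 reads in chr8A and 20 and 33 in the clones (ratios of 10.4, interval 2.52 to 91.6, and 16.5, interval 4.21 to 142). ERK output genes rose, 11 of 19 in each clone with 1 falling in clone 1 (12 and 1, and 11 and 0, adjusted over the list alone; adjusted p = 6.96e-13 and 1.49e-09, and 0.00343 and 0.00913 with an estimated correlation). Spry4 rose by 3.14 ± 0.13 and 2.64 ± 0.14, from 4.21 ± 0.617 CPM in chr8A to 37.0 ± 3.17 and 26.2 ± 2.88 (mean ± SD, n = 2 each). The ETS factor gene Etv4 rose by 1.84 ± 0.11 and 1.45 ± 0.12, Myc by 1.51 ± 0.12 and 1.14 ± 0.13, and Dusp6 by 1.34 ± 0.14 and 1.20 ± 0.15. Genes of DNA methylation rose, 5 of 9 in clone 1 and 4 in clone 2 with 1 falling in each (the same adjusted over the list alone; adjusted p = 4.54e-06 and 0.000116, and adjusted p = 0.0429 and 0.0624 with an estimated correlation). The cofactor gene Dnmt3l rose by 0.96 ± 0.041 and 0.92 ± 0.041. Germline genes lay higher, with 5 of 15 rising and 2 falling in clone 1 and 4 rising and 1 falling in clone 2 (5 and 2, and 4 and 2, adjusted over the list alone; adjusted p = 0.00509 and 0.00346, and 0.0429 and 0.0419 with an estimated correlation). Both germline calls ended without the count filter (adjusted p = 0.0653 and 0.0619; lowest over the camera settings 0.00187 and 0.000843). The X-linked homeobox gene Rhox5 rose most of them, by 3.08 ± 0.093 and 3.31 ± 0.091. As lists, naive and formative pluripotency genes did not pass in SL2i (adjusted p = 0.88 and 0.271 in clone 1, 0.825 and 0.528 in clone 2). Their members went both ways. Of 18 naive genes, 8 rose and 7 fell in clone 1, and 7 rose and 6 fell in clone 2 (9 and 8, and 8 and 6, adjusted over the list alone). Of 12 formative genes, 2 rose and 2 fell in clone 1, and 2 rose and 3 fell in clone 2 (4 and 2, and 2 and 4).

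Lists of lipid and amino acid genes lay lower in SL2i. Of 14 fatty acid synthesis genes, 8 fell in each clone (9, and 8 with 1 rising, adjusted over the list alone; adjusted p = 3.06e-06 and 2.8e-06, and 0.00904 and 0.00923 with an estimated correlation). They included Scd1 (-0.63 ± 0.043 and -0.65 ± 0.043; 8.45% shared) and the citrate lyase gene Acly (-0.26 ± 0.035 and -0.28 ± 0.035). Of 30 ATF4 genes, 11 fell and 2 rose in each clone (the same adjusted over the list alone; adjusted p = 0.000805 and 0.000576, and adjusted p = 0.219 and 0.231 with an estimated correlation). Pck2, a mitochondrial PEP carboxykinase gene, stood at -0.67 ± 0.063 and -0.70 ± 0.063, and Psat1 at -0.45 ± 0.038 and -0.32 ± 0.037. Of 23 genes of pyruvate and lactate transport and use, 7 fell and 2 rose in clone 1 and 4 fell and 1 rose in clone 2 (the same adjusted over the list alone; adjusted p = 0.00365 and 0.00346, and adjusted p = 0.0643 and 0.0624 with an estimated correlation). Both calls also ended when members with at least 5% shared words were left out (adjusted p = 0.3 and 0.249), and that of clone 2 ended without the count filter (adjusted p = 0.137). The lowest over the camera settings were 0.00105 and 9e-04. The list holds Slc16a1 itself, which was among the falls in each clone. The lactate dehydrogenase gene Ldhb, which converts lactate and pyruvate, stood at -1.62 ± 0.048 and -1.48 ± 0.047 (33.8% shared, uncertain). Pdk1 rose by 0.43 ± 0.065 and 0.32 ± 0.066.

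Of 17178 genes, 3853 passed in clone 1 (1780 higher, 2073 lower) and 3531 in clone 2 (1673 higher, 1858 lower) in SL2i, and 270 and 250 were at least 2-fold higher, 291 and 256 at least 2-fold lower. Car4, without a read in chr8A, was at least 5.88-fold higher in clone 1 and 7.99-fold in clone 2 against 3 reads over the group. The imprinted gene Igf2 rose by 3.81 ± 0.18 and 3.93 ± 0.17, from 2.98 ± 0.391 CPM to 41.9 ± 4.75 and 45.4 ± 0.462 (mean ± SD, n = 2 each). Csf1 rose in clone 2, with 18 reads against 2 (ratio 8.98, interval 2.15 to 79.8), and without SL2i chr8A replicate 1 or clone 2 replicate 2 it did not pass (range 0.0016 to 0.1). The genes that fell most in both clones were Peg3 (-2.13 ± 0.061 and -2.27 ± 0.061), Cspg4b (-1.99 ± 0.093 and -1.90 ± 0.090) and the collagen gene Col9a2 (-1.84 ± 0.22 and -2.56 ± 0.24). They were followed by the Nodal antagonist gene Lefty1 (-1.73 ± 0.12 and -2.11 ± 0.13; 25.6% shared), Evc (-1.60 ± 0.46 and -2.11 ± 0.50) and Duxbl1 (-1.65 ± 0.25 and -1.70 ± 0.25; 96.0% shared, uncertain). The Evc call in clone 1 ended without SL2i clone 1 replicate 1 (adjusted p = 0.15; range 0.0051 to 0.15). Dtna, Nalf2 and Klk8 fell in clone 1 (-2.07 ± 0.38, -1.88 ± 0.42 and -1.79 ± 0.34). In clone 2 Plagl1 fell by 3.21 ± 0.058. There Gap43 had 1 read against 13 (13.0-fold lower, interval 1.96 to 553), a call that ended under DESeq2 and without SL2i chr8A replicate 2 or clone 2 replicate 1 (range 0.0055 to 0.11). The clones shared 2690 calls of the same sign (1237 higher, 1453 lower) and 2 of opposite sign, against 173.4 and 224.2 for independent lists and at most 1 in simulated unchanged groups. The correlation across genes of at least 3 log2 CPM was 0.864 with a covariance of 0.108, against means of 0.481 and 0.014 (highest 0.594 and 0.0192) in the simulations, and 2 controls could not be split. As in SL, the simulations held no differences between lines.

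**Figure D3:**
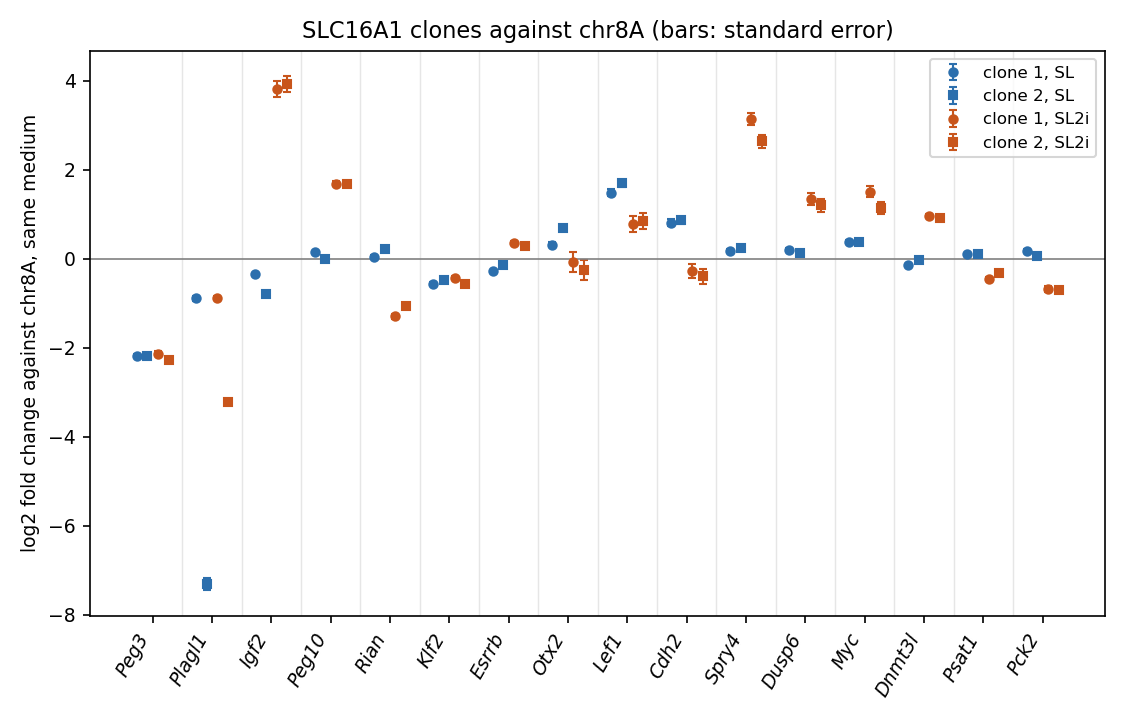
Log2 fold change of 16 named genes in each SLC16A1 clone against chr8A of the same medium, with bars for the standard error. Peg3 lay between -2.27 and -2.13 in all 4 comparisons, while Igf2 lay below 0 in SL and at 3.81 and 3.93 in SL2i.

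The clones were then compared with each other, which shows what differs between lines labeled with the same gene. Of the genes named by the rule, Plagl1 differed most in both media, lower in clone 2 by a log2 fold change of -6.44 ± 0.15 in SL and -2.33 ± 0.061 in SL2i. Slc16a1 was lower in clone 2 by -0.87 ± 0.035 and -0.64 ± 0.055, the imprinted gene Zrsr1 by -0.80 ± 0.091 and -0.70 ± 0.12, and the ubiquitin ligase gene Mycbp2 by -0.70 ± 0.036 and -0.58 ± 0.073. Ndufa4, a subunit of cytochrome oxidase, was higher in clone 2 by 0.76 ± 0.032 and 0.83 ± 0.044, and its neighbor Phf14 by 0.72 ± 0.043 and 0.85 ± 0.065 (16.7% shared). In SL, clone 2 also had less Trim67 (-0.55 ± 0.075) and Pmp22 (-0.53 ± 0.095) and more Mcf2 (0.43 ± 0.078) and Krt42 (0.37 ± 0.085; 5.62% shared). Tmem40 and Panct2 were higher by 0.65 ± 0.14 and 0.55 ± 0.13, calls that ended at equal depth (adjusted p = 0.15 and 0.47; lowest over all settings 0.00021 and 0.0023). In SL2i, Spry4 was lower in clone 2 by -0.50 ± 0.084, but not without SL2i clone 1 replicate 2 (adjusted p = 0.098; lowest 5.9e-06). Small rises of Dld, Rian, Atp6v1a and Anp32a in SL2i, of 0.26, 0.25, 0.17 and 0.17, ended under 4, 5, 12 and 18 of the settings tried, with highest adjusted p of 0.32, 0.42, 0.44 and 0.4 and lowest of 0.0058, 0.0059, 0.0088 and 0.004.

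As groups, trophoblast genes were lower in clone 2 than in clone 1 in SL, with 4 of 9 falling (5 adjusted over the list alone; adjusted p = 2.87e-15, and 0.00775 with an estimated correlation). Krt19 stood at -0.35 ± 0.042 and Krt18 at -0.42 ± 0.037 (12.4% shared). Of 17 p53 targets 7 fell (9 with 1 rising adjusted over the list alone; adjusted p = 1e-06, and 0.0109 with an estimated correlation), including Perp at -0.22 ± 0.037 and Phlda3 at -0.21 ± 0.040. Of 25 cholesterol synthesis genes 5 fell (10 adjusted over the list alone; adjusted p = 9.15e-07, and 0.0142 with an estimated correlation), led by Msmo1 at -0.16 ± 0.035. Formative genes were higher, 6 of 12 (7 adjusted over the list alone; adjusted p = 3.2e-07, and 0.0176 with an estimated correlation), with Otx2 at 0.36 ± 0.056. So were naive genes, 4 of 18 (8 adjusted over the list alone; adjusted p = 3.27e-05, and 0.0126 with an estimated correlation), with Esrrb at 0.16 ± 0.030. In all, 756 genes passed in SL (291 higher and 465 lower in clone 2) and 27 in SL2i (15 higher, 12 lower). Another scaling moved these splits: under RLE factors the share of higher calls went from 38.5% to 27.3% in SL and from 55.6% to 42.9% in SL2i. The SL count was 386 in DESeq2, 419 at equal depth and 1223 with only the groups compared in the fit, where the SL2i count was 11. It fell to 393 without clone 1 replicate 1, 468 without clone 1 replicate 3, 491 without clone 2 replicate 1 and 371 without clone 2 replicate 3, and the SL2i count to 16 without SL2i clone 1 replicate 2.

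Whether the clones differ from chr8A by more in one medium than in the other was tested as an interaction, where a value above 0 means a higher fold change in SL2i. ERK output genes had higher fold changes in SL2i, with 9 of 19 above 0 and 1 below in each clone (9 and 2, and 10 and 1, adjusted over the list alone; adjusted p = 1.67e-08 and 8.12e-05, and 0.0179 and 0.0472 with an estimated correlation). The interaction was 2.96 ± 0.13 and 2.40 ± 0.14 for Spry4, 1.68 ± 0.12 and 1.29 ± 0.12 for Etv4, and 1.14 ± 0.15 and 1.07 ± 0.15 for Dusp6. Trophoblast genes did likewise, 6 of 9 in each clone (6 and 7 adjusted over the list alone; adjusted p = 1.67e-08 and 7.59e-13, and 0.028 and 0.0132 with an estimated correlation). Against chr8A in SL, 3 of these 9 rose and 1 fell in clone 1 (camera adjusted p = 0.175). In clone 2 in SL, 5 fell (adjusted p = 0.000724, and 0.0918 with an estimated correlation). Krt18 had interactions of 2.40 ± 0.16 and 2.78 ± 0.16 (12.4% shared). ATF4 genes had lower fold changes in SL2i. In clone 1, 12 of 30 were below 0 and 1 above, and in clone 2, 14 below and 2 above (13 and 1, and 17 and 2, adjusted over the list alone; adjusted p = 2.91e-09 and 1.21e-07, and adjusted p = 0.0331 and 0.0668 with an estimated correlation). Psat1 stood at -0.55 ± 0.047 and -0.42 ± 0.046 and Pck2 at -0.83 ± 0.076 and -0.77 ± 0.075. Genes of pyruvate and lactate transport and use were lower, 8 of 23 in each clone with 2 and 1 above (10 and 2, and 9 and 1, adjusted over the list alone; adjusted p = 0.00132 and 0.00418, and adjusted p = 0.0378 and 0.0668 with an estimated correlation). Both of these calls ended when members with at least 5% shared words were left out (adjusted p = 0.31 and 0.37; lowest over the camera settings 0.00094 and 0.0039). Ldhb stood at -1.14 ± 0.061 and -1.09 ± 0.059 (33.8% shared, uncertain) and Emb at -0.75 ± 0.10 and -0.70 ± 0.097. Slc16a1, also a member, was among those below 0 in clone 1. Of 9 genes of DNA methylation, 4 were above 0 in clone 1 and 3 in clone 2, with 1 below in each (the same adjusted over the list alone; adjusted p = 2.89e-06 and 0.0423, and adjusted p = 0.0314 and 0.239 with an estimated correlation), with Dnmt3l at 1.09 ± 0.050 in clone 1. The DNA methylation call of clone 2 also ended without the count filter and without members of at least 5% shared words (adjusted p = 0.0842 in the latter; lowest over the camera settings 0.0303). Of 18 naive genes, 7 were above 0 and 3 below in clone 1 (9 and 3 adjusted over the list alone; adjusted p = 6.89e-05, and 0.0314 with an estimated correlation). For clone 2 only the 15 members under 5% of shared words are given, a subset chosen after the data were seen. Of these, 5 were above 0 and 2 below (camera adjusted p = 0.0387). The 12 formative genes did not pass as a list in clone 1, with 1 above 0 and 4 below (camera adjusted p = 0.141). Of the 11 under 5% of shared words, 4 were below 0 in clone 1 and 7 in clone 2, with 0 above (camera adjusted p = 0.0233 and 0.000159). Of 17 p53 targets, 6 were above 0 in clone 1 and 8 in clone 2, with 1 below in each (6 and 1, and 9 and 1, adjusted over the list alone; adjusted p = 0.0451 and 0.000215, and adjusted p = 0.163 and 0.0472 with an estimated correlation), with Pmaip1 at 0.56 ± 0.062 in clone 2.

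Of single genes, Igf2 had an interaction of 4.16 ± 0.18 in clone 1 and 4.71 ± 0.17 in clone 2, and Esrrb one of 0.65 ± 0.046 and 0.41 ± 0.045. For Plagl1 in clone 2 it was 4.10 ± 0.21. Car4 and Krt7 also led by size, but no fitted value is given here because chr8A in SL2i had no read of Car4 and 2 of Krt7. The interaction of Slc16a1 was -0.18 ± 0.060 in clone 1 (adjusted p = 0.020) and 0.04 ± 0.063 in clone 2 (adjusted p = 0.76). The former call ended under DESeq2 (adjusted p = 0.073) and without SL chr8A replicate 1 (0.053), SL clone 1 replicate 2 (0.17), SL2i chr8A replicate 2 (0.23), SL2i clone 1 replicate 1 (0.098) or SL2i clone 1 replicate 2 (0.095). Interactions passed for 2925 genes in clone 1 (1337 above 0, 1588 below) and 2898 in clone 2 (1321 above, 1577 below), and 856 were above and 1061 below 0 in both with 0 of opposite sign. In all 4 comparisons with chr8A, 220 genes were higher and 301 lower.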

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

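Of the tests that weigh explanations in this part, those on SL cells or RNA and on chr8A standing apart were chosen only after the result was seen. An interaction term singled out each value here, meaning that the effect of a clone against chr8A differed between SL and SL2i. Such a term passed for 2925 genes in clone 1 and 2898 in clone 2 (edgeR, Benjamini-Hochberg). In clone 1 the log2 interaction was 2.96 for Spry4, 1.68 for Etv4, 1.14 for Dusp6, 2.40 for Krt18 (12.4% shared), 3.56 for Krt7, 4.16 for Igf2, 1.09 for Dnmt3l and 0.65 for Esrrb. It was -1.14 for Ldhb (33.8% shared), -0.75 for Emb, -0.83 for Pck2, -0.55 for Psat1 and -0.18 for Slc16a1. In clone 2 it was 2.40 for Spry4, 1.29 for Etv4, 1.07 for Dusp6, 2.78 for Krt18, 4.65 for Krt7, 4.71 for Igf2, 4.10 for Plagl1, 0.56 for Pmaip1 and 0.41 for Esrrb. It was -1.09 for Ldhb, -0.70 for Emb, -0.77 for Pck2 and -0.42 for Psat1. Car4 gave 7.03 and 7.56, values that depend on a prior count and are no bounds. Those of Krt7 rest on 2 reads of chr8A in SL2i and are imprecise.

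As lists, the adjusted p of the interaction in clones 1 and 2 was 1.67e-08 and 8.12e-05 for ERK output, and 1.67e-08 and 7.59e-13 for trophoblast genes. It was 2.91e-09 and 1.21e-07 for ATF4 genes, and 0.00132 and 0.00418 for pyruvate and lactate transport and use. It was 2.89e-06 and 0.0423 for DNA methylation machinery, and 0.0451 and 0.000215 for p53 targets. With an estimated correlation the ATF4 and the pyruvate and lactate calls held in clone 1 (adjusted p = 0.0331 and 0.0378) and ended in clone 2 (0.0668 each). Those of DNA methylation in clone 2 and p53 targets in clone 1 ended too (0.239 and 0.163). The pyruvate and lactate calls also ended in both clones without members of at least 5% shared words (0.31 and 0.37).

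Some of these genes lay toward their SL level in the clones kept in SL2i, such as Spry4 at 37.0 and 26.2 CPM against 4.21 in SL2i chr8A and 138 in SL chr8A. Others lay further from it: Psat1 and Emb were lower in SL2i than in SL (-0.94 and -3.43) and lower again in clone 1 (-0.45 and -0.55) and clone 2 (-0.32 and -0.35) in SL2i. As lists, naive and formative pluripotency genes did not pass in either clone in SL2i, but naive members moved both ways. Of 18 naive genes, 8 rose and 7 fell in clone 1, and 7 rose and 6 fell in clone 2. SL cells or RNA in the clone libraries is argued against. The 556 and 550 genes higher in both clones and lower in SL2i than in SL, with under 5% of shared words, would need a median of 38.1% and 35.8% of the SL level, while Acta2, Enpp2, Car4 and Myl9 allow at most 0.411 to 3.70% in clone 1 and 0.502 to 3.78% in clone 2. A weaker response of the clones to SL2i stayed open. With a separate chr8A library on each side, 60.2 to 61.5% of the 2690 genes called in both clones moved toward SL. For all 10305 genes of at least 3 log2 CPM it was 52.7 to 54.4%. The 2690 genes were chosen with both chr8A libraries, so the sides were not fully separate and their share may be too high. Both clones gave the same counts, 1654 and 1620, and are no separate tests. In SL2i the clones differed from each other at only 27 genes, against 3853 and 3531 between clones 1 and 2 and chr8A. On component 2 (3.1% of variance) the chr8A libraries lay at 42.75 and 39.58 and the clones at -21.84 to -19.91. This met the mark set for chr8A rather than the clones standing apart. A change shared by both clones would give the same values, so the test could not decide between them. With 1 control line, the lines and the altered gene cannot be told apart.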

How the results depend on the processing

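No named gene turned its direction under any alternative, and no named list did over the camera settings. Fry was left out of that tally, and lists were not tested in DESeq2 or with 1 library left out. The balance of higher and lower calls turned in 1 of 23 settings for clone 1 and 9 for clone 2 in SL. It turned in 13 between the clones in SL2i and in 2 and 3 for the interactions. Of 211 named gene values, the comparisons under other settings kept their call 1609 times, lost it 19 times and gained it 10 times. With 1 library left out these numbers were 3022, 52 and 1. Calls of 56 of the named list results were kept 301 times and lost 34 times over the camera settings. Where a count moved, the cause was not tested, except that fewer libraries or reads give less power by construction. The 6 genes called between LbNOX and vector became 24 without a filter, 14 with DESeq2, 49 without both libraries at the far end of component 1 (chosen after the data were seen) and 0 to 13 with 1 library left out. DESeq2 called 1774 genes for clone 1 in SL (2850 in edgeR), 2876 for clone 2 (4618), 386 between the clones in SL (756) and 1338 for both clones in SL (2103). Equal depth, also chosen after the data were seen, gave 1854, 2900, 419 and 1288. With only the groups compared in the fit, the clones differed at 1223 genes in SL and 11 in SL2i (27), and with 1 library left out at 371 to 831 and 16 to 40. Other counts with 1 library left out ranged from 11243 to 12683 for the media, 2031 to 2910 and 3667 to 4602 for the clones in SL, 2572 to 3941 and 2358 to 3625 in SL2i, and 2010 to 2960 and 2142 to 2838 for the interactions. SL2i groups then held 1 library, which was assumed to vary like the other groups. The interaction of Slc16a1 in clone 1 was -0.18 in DESeq2 (adjusted p = 0.073) and -0.22 to -0.13 with 1 library left out. Lists called with an estimated correlation went from 2 to 0 between LbNOX and vector, 17 to 4 for the media, 7 to 4 and 12 to 7 for clones 1 and 2 in SL, 11 to 5 and 11 to 4 in SL2i, 14 to 9 and 3 to 0 between the clones, and 11 to 3 for the interaction of clone 2. Fry, which tests a list against no change and not against other genes, called 0 lists between LbNOX and vector, 12 for clone 1 in SL, 18 for clone 1 in SL2i, 1 between the clones in SL2i and 16 for the interaction of clone 1. A block for the replicate number left 3 calls between LbNOX and vector and ended the Wnt calls of the media and of clone 2 in SL and the DNA methylation call of the interaction in clone 2. The numbers gave little sign of pairing the samples. With the mean of each group taken off, LbNOX and vector libraries of the same number correlated at 0.392, -0.506 and -0.318. Vector replicate 2 and LbNOX replicate 3 correlated at 0.685. Such differences sum to 0 within a group, so some negative values arise by construction. In the other table, same-number correlations lay from -0.074 to 0.113, those within SL2i being 0.065, 0.076 and 0.036. In SL2i, with fewer reads and libraries, 65.7% of planted 1.5-fold changes were found against 79.1% in SL.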

Other observations

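In this part, the test on fewer cells with a Y chromosome was chosen only after the result was seen. Genes that differed between the clones in both media included neighbors on chromosome 6. Thsd7a lay beside Ndufa4 and Phf14 and was higher in clone 2 with them, by 1.28 in SL and 4.11 in SL2i, while the next genes on either side, Ica1 and Tmem106b, did not pass (adjusted p = 0.70 and 0.38 in SL). Samd9l, elsewhere on chromosome 6, was higher by 1.99 and 2.37. Of the 10 genes called the same way in both media (6 higher, 4 lower in clone 2) 2 pairs were adjacent. The cause was not tested.

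Y-linked genes were low in the vector and LbNOX cells next to the other lines, in tables normalized separately and without a test. Ddx3y stood at 6.66 and 1.47 CPM in vector and LbNOX cells and at 99.2 in chr8A in SL. Uty stood at 6.62, 1.91 and 49.7, and the translation factor gene Eif2s3y at 16.8, 10.6 and 96.4. Eif2s3y and the X-linked gene Rhox5 did not pass between LbNOX and vector (-0.67 ± 0.12 and -1.90 ± 0.30, adjusted p = 0.10 and 0.065; ranges over all settings 3.7e-06 to 0.69 and 3.2e-09 to 0.62). Of 20 chromosomes, 11 passed the chromosome check between LbNOX and vector, which sets the median of a chromosome's genes against random gene sets. It treats genes and not libraries as replicates, so passing does not measure the spread between libraries. In the same check 9 passed for the media, 9 and 8 for clones 1 and 2 in SL, and 0 between the clones in SL. Chromosome 8 was furthest from 0 and lay slightly higher in LbNOX cells, with a median of 0.074 over 826 genes (0.072 with RLE factors) against -0.003 for the others. Pou4f2 and the endoderm example Col4a1, higher by 0.56 and 0.24, lie on chromosome 8. Whether their rises belong to this shift was not tested.

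The 5 genes lower in LbNOX cells were all sex-linked, 3 on X and 2 on Y (562 and 6 tested). A lower dosage of the whole X chromosome is argued against, since the median of X-linked genes was -0.014. If fewer cells carried a Y chromosome, and cells without it gave no such reads, all Y-linked genes would fall alike. The log2 fold change of Eif2s3y, with 0.28% of its words shared, lay 1.32 ± 0.18 above the mean of Ddx3y and Uty. Whether cells without a Y chromosome gave reads of these genes was not tested, and the levels were low, so this explanation stayed open. No biological explanation was tested beyond these.

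Respiratory chain genes higher in SL2i were weighed against shared sequence. Reads on 893 annotated pseudogenes made up 0.905 to 0.960% of counts in the SL libraries of the LbNOX table, 0.908 to 0.952% in those of the other table and 0.238 to 0.255% in SL2i, a ratio of 3.78. That ratio is in line with reads from near-identical copies being assigned differently in the SL2i and SL libraries. An effect of the medium on respiratory chain genes as a class is argued against as the source of the largest values, because members with at least 20% of shared words lay 1.08 above those under 5% (permutation p = 1e-05, the smallest possible). The members under 5% still lay higher, with 32 of 39 rising (camera adjusted p = 0.000178).

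Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. For LbNOX against vector 2 of 10 splits gave as many calls as the real one, 6, and the highest other gave 491. That split set vector replicate 1 and LbNOX replicates 1 and 2 against the rest, which points to a structure of the samples other than LbNOX. On component 1 (30.1% of variance) vector replicate 2 and LbNOX replicate 3 lay at 22.26 and 22.37 and the others at -13.66 to -8.23. Only the real split, 1 of 10, gave as many calls for clone 1 (2850, highest other 0), clone 2 (4618, highest other 0) and the clones against each other (756, highest other 1) in SL.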
